A study of Halobacterium salinarum NRC-1 with 8 samples.

How the data were processed

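Total RNA of 4 cultures of the archaeon Halobacterium salinarum NRC-1, labelled as knockouts of ura3 and sop2, was compared with RNA of a standard mid-log reference of NRC-1 on 8 spotted arrays with 2 colours. Per the labels, cultures of 50 mL in flasks of 125 mL were grown in rich medium to mid-log phase, at high oxygen (shaking at 210 rpm) or low oxygen (100 rpm in a stoppered flask) and in light or in dark. Each culture was hybridised on 2 arrays with the dyes exchanged, so that replicate 1 carried the culture in Alexa 532 and replicate 2 carried it in Alexa 647. Both arrays of a culture hold the same RNA and counted as 1 replicate, which leaves 1 culture for each combination of oxygen and light.

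The deposited scanner files give, per the file headers, the intensity of every spot and of its local background in both channels, each scanned at a high and a low setting. The scanner, the spot-finding program and its version are not given in the sources used here. The spot confidence in the deposited files is a score between 0 and 100, per the file headers. Spots with a score under 50 were the brightest ones, with a median in their brighter channel between 51311 and 58256 intensity units, so that all spots were kept. Leaving these out had been planned for the reported results and was run as an alternative. Keeping all spots also kept saturated ones. On the high scan 46 to 155 spots of an array were saturated in Alexa 532 and 64 to 377 in Alexa 647. The authors' value table holds log10 ratios whose scale and direction were found by comparison with the scanner values. They follow the log10 of Alexa 532 over Alexa 647 of the high scan without background subtraction (r between 0.960 and 0.996, slopes between 0.984 and 1.03), not turned by dye and not centred. The medians of the authors' 8 log10 columns were 0.124, 0.157, 0.132, 0.125, 0.107, 0.119, 0.154 and 0.102. The authors left 594 to 645 of the 10752 spots of each array empty, and the rule for this is not given in the sources used here.

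Spots of the scanner files were matched to the rows of the authors' log10 table by their position on the array, row by row. Matching by the spot number of the scanner files gave r between 0.125 and 0.251 and was not used. Every probe lies on 4 spots, as 2 neighbours and again in the lower part of the array, and these were averaged to 2688 features. Neighbouring spots of a feature correlated at 0.982 to 0.991 in the Alexa 647 intensity, and the upper and lower copies at 0.861 to 0.912. The platform annotation used here names 133 features (532 spots with 1 symbol, 0 with several). The remaining 10220 spots, or 2555 features, are unnamed here, so most of the genome enters the tests without a gene name.

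Ratios were computed in R 4.3.3 with limma 3.58.1. Spot means of the high scan were corrected with normexp (offset 50) on the median local background and normalised within each array by loess. The log2 ratios were turned to culture over reference by the dyes in the labels, and averaged over spots and then over the dye orientations of a culture. limma's lmFit and eBayes fitted additive terms for oxygen and light over the 4 cultures, with 1 residual degree of freedom and 4.04 prior degrees of freedom. This fit takes the interaction of oxygen and light, together with the spread between cultures, as its error. Changes are given as low minus high oxygen and as light minus dark, with the standard error (SE) of that fit, and p-values were adjusted by Benjamini-Hochberg over all features at a threshold of 0.05. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

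Of 21 gene lists matched by symbol, 15 had at least 1 named member and 4 had the 5 members needed for limma's camera test (preset correlation 0.01). camera was repeated with an estimated correlation. That repeat rests on the 1 residual degree of freedom alone, so that it can hardly pass any list and decides little. Each list's median was also placed among 10000 random lists matched on intensity. The deleted genes were left out of the lists. A further pair of lists, aminoacyl-tRNA synthetases and histidine synthesis, was added after the gene names were seen. The named genes are sop2, pyrF (ura3), htr2, sop1 and htr1. To these come, for each factor, up to 10 genes in each direction that passed the test with 1 sign in every stratum and orientation. Where too few passed, the places were filled with the largest changes having the same sign in 4 of 4 array differences. The 4 largest changes of each list, and the 5 highest and 5 lowest interaction values with 1 sign in both orientations, complete the set. Genes without usable signal are not named. Usable means a culture signal over 1.5 times the local background on at least 1 array of every culture, which held for 1521 features, 102 of them named. A stricter set, over 1.5 times the background in both channels on all 8 arrays, held 539 features and is called the bright features.

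The groups, lists, fits, named-gene rule and most alternatives were fixed before the data were examined. The match by position, the high scan and spot mean, the factor of 1.5, keeping spots of low confidence, the dye-adjusted fit used when an array is left out, and the alternatives of a low-gain scan, the authors' empty spots, bright features alone and named features alone were chosen after the data had been seen. Further alternatives changed the background correction, normalisation, spot averaging, variance prior, threshold and source of values, took arrays as observations, left out each array or used a single dye orientation.

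Signal over background limits the precision. The median spot in Alexa 532 lay between 1219 and 3947 intensity units on a median background of 958 to 3930, and 25.0% to 56.6% of the spots of an array were below their background in this dye, against 6.53% to 14.8% in Alexa 647. The file headers give no slide or scan date. The arrays of each dye orientation carry consecutive array numbers in the labels, so that a dye effect and a difference between print or hybridisation runs cannot be told apart, and every culture has 1 array of each. The scripts were tested on simulated data with the prior variance of the real fit and 200 changed features among 2688 (20 runs). For oxygen, 10.2% of features with a log2 change of 0.5 were recovered, 84.4% at 1 and 99.4% at 2. For light the shares were 7.62%, 79.1% and 99.1%. These shares hold only beside 200 changed features, which loosen the adjustment for multiple tests. Where fewer features change, more are missed, so that 0 calls in the real data would not exclude changes of these sizes. In the real fit for oxygen, features at 1.13 ± 0.18 and 0.95 ± 0.14 (SE) did not pass. Wrong calls averaged 10.8 per run for oxygen and 9 for light. A list of 7 members was called in 2% of 100 runs without a shift, in 94% at a shift of 0.3 and in 100% at 0.5. The simulated features were independent of each other and all 7 members shifted equally. For correlated members or unequal shifts these shares do not hold.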

Results

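The data describe how transcript levels of Halobacterium salinarum, a halophilic archaeon that swims, respires oxygen and uses retinal proteins as light sensors and ion pumps, differ with oxygen and light in a strain labelled as lacking sensory rhodopsin II. The 4 cultures were grown in high oxygen and light, high oxygen and dark, low oxygen and light, and low oxygen and dark. Each was measured on 2 arrays against a common reference, and the number of cultures, 1 per combination, limits the precision beside the signal over background. The spread that enters the tests is what is left after additive effects of oxygen and light were removed. It holds the interaction of oxygen and light, differences between single cultures and measurement error, which cannot be separated there.

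The deleted genes of the labels came first. The sop2 spots, for sensory rhodopsin II, gave a mean log2 ratio of culture over reference of 0.10 ± 0.15 (SD, n = 4 cultures). The values were 0.08 in high oxygen and light, −0.11 in high oxygen and dark, 0.19 in low oxygen and light and 0.23 in low oxygen and dark. This placed sop2 at percentile 64.3 of all 2688 features, and on the low-gain scan its mean was −0.071. With the culture in Alexa 647, the sop2 signal was 2.52 to 5.11 times the local background, and that of the reference in the same dye was 3.09 to 5.14 times. With the culture in Alexa 532, its sop2 signal was 1.02 to 1.44 times the background. No depletion of sop2 was therefore seen in cultures labelled as its deletion. Where the probe lies relative to the deleted part is not given in the sources used here, and a probe outside it would check nothing. The cultures are for this reason called cultures labelled as sop2 deletion.

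The pyrF spots, for orotidylate decarboxylase (ura3), gave −0.28 ± 0.29 (SD, n = 4 cultures), at percentile 9.23. In Alexa 647 the pyrF signal was 1.56 to 3.13 times the background for the cultures and, on the other 4 arrays, 1.34 to 1.72 times for the reference. The arrays with the culture in Alexa 647 had a mean ratio of −0.04 ± 0.23 (SD, n = 4 arrays). Their reference, in Alexa 532, lay at only 1.04 to 1.22 times the background, so that this ratio could hardly show a depletion. With the culture in Alexa 532 its pyrF signal was below the background on all 4 arrays, at 0.553 to 0.901 times, and these arrays had a mean of −0.51 ± 0.69. The mean of pyrF was 0.060 without background correction, 0.20 with plain subtraction and 0.13 on the low-gain scan. The transducer gene htr2, partner of sop2, lay at −0.10 ± 0.05. The genes of sensory rhodopsin I and its transducer, sop1 and htr1, lay at −0.01 ± 0.13 and −0.04 ± 0.03 (SD, n = 4 cultures each).

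**Figure D1:**
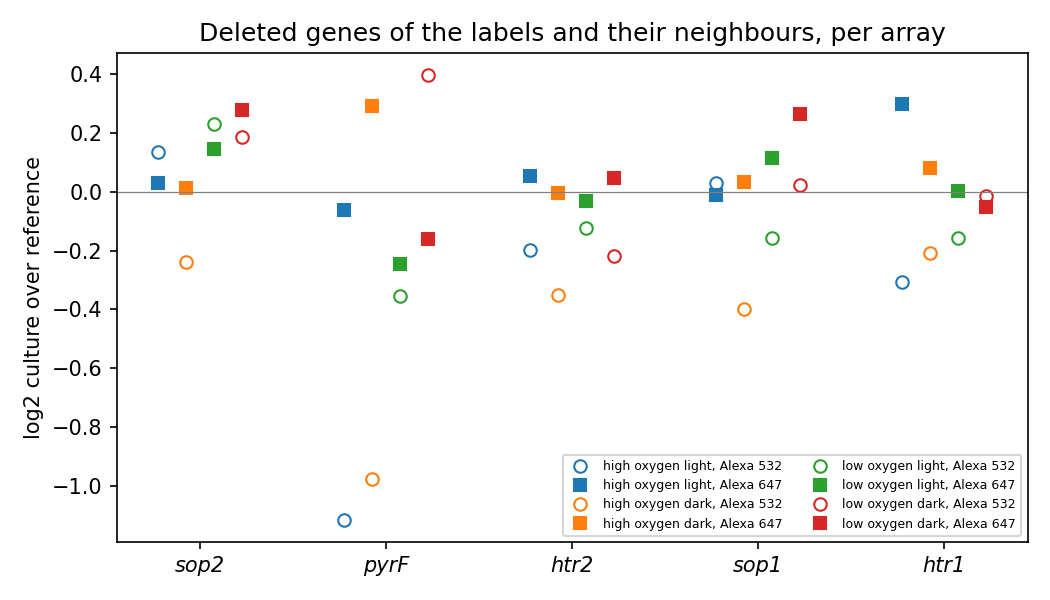
Log2 ratio of culture over reference on each of the 8 arrays for sop2, pyrF and their neighbours htr2, sop1 and htr1; colours mark cultures, open circles arrays with the culture in Alexa 532 and filled squares those with it in Alexa 647. The sop2 points lie around 0, with culture means between −0.11 and 0.23, and pyrF spreads most.

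The first comparison asks which genes differ between low and high oxygen. Of the named genes with usable signal and 1 sign in all 4 array differences, phoU had the highest log2 change (low minus high oxygen). This gene, for a regulator of phosphate uptake, stood at 0.39 ± 0.15 (SE, 1.31-fold). arcA, for the arginine deiminase of fermentative arginine use, followed at 0.31 ± 0.15 (1.24-fold). sop2 stood at 0.23 ± 0.14, glnA (glutamine synthetase) and thiD (thiamine synthesis) at 0.20 ± 0.13 each. At the other end, purF, for the amidotransferase that opens purine synthesis, had −0.39 ± 0.14 and glmS, for glucosamine phosphate synthesis, −0.28 ± 0.14. None of these passed the test, with n = 4 cultures and an adjusted p of 0.680 or more in limma. In the authors' table phoU had 0.014, arcA 0.089 and purF −0.043. With 1 array left out phoU ran from 0.22 to 0.57, purF from −0.54 to −0.24 and glmS from −0.42 to −0.14.

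limma called 0 of 2688 features for oxygen at an adjusted p of 0.05, and 181 had an unadjusted p under 0.05, where chance gives 134.4. The lowest adjusted p was 0.680. The same sign in all 4 array differences was found for 348 features (12.9%). Independent signs would give 12.5%, and spread between single cultures, which both arrays of a culture share, gives more. Among named genes with usable signal 12 had it, 8 above and 4 below 0. Besides those given, proS and ileS, for prolyl- and isoleucyl-tRNA synthetase, had 0.16 ± 0.14 and 0.15 ± 0.14, and cbiQ of the cobalt uptake system had 0.10 ± 0.13. Under 1 alternative each, thiD turned to −0.043, proS to −0.027 and ileS to −0.20. htr4 and htr8, both for taxis transducers, had −0.23 ± 0.14 and −0.19 ± 0.14. In the authors' table htr4 had −0.0019, cbiQ 0.00052 and glnA 0.046, while htr8 had −0.17 and sop2 0.21. The largest changes with 1 sign in all array differences came from the unnamed features that start at spots 4845 and 4813, with 1.13 ± 0.18 and 0.95 ± 0.14 (adjusted p = 0.680 each). Without low-oxygen light replicate 1, both of these passed, with an adjusted p of 0.0349, and the count of features called was 2.

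**Figure D2:**
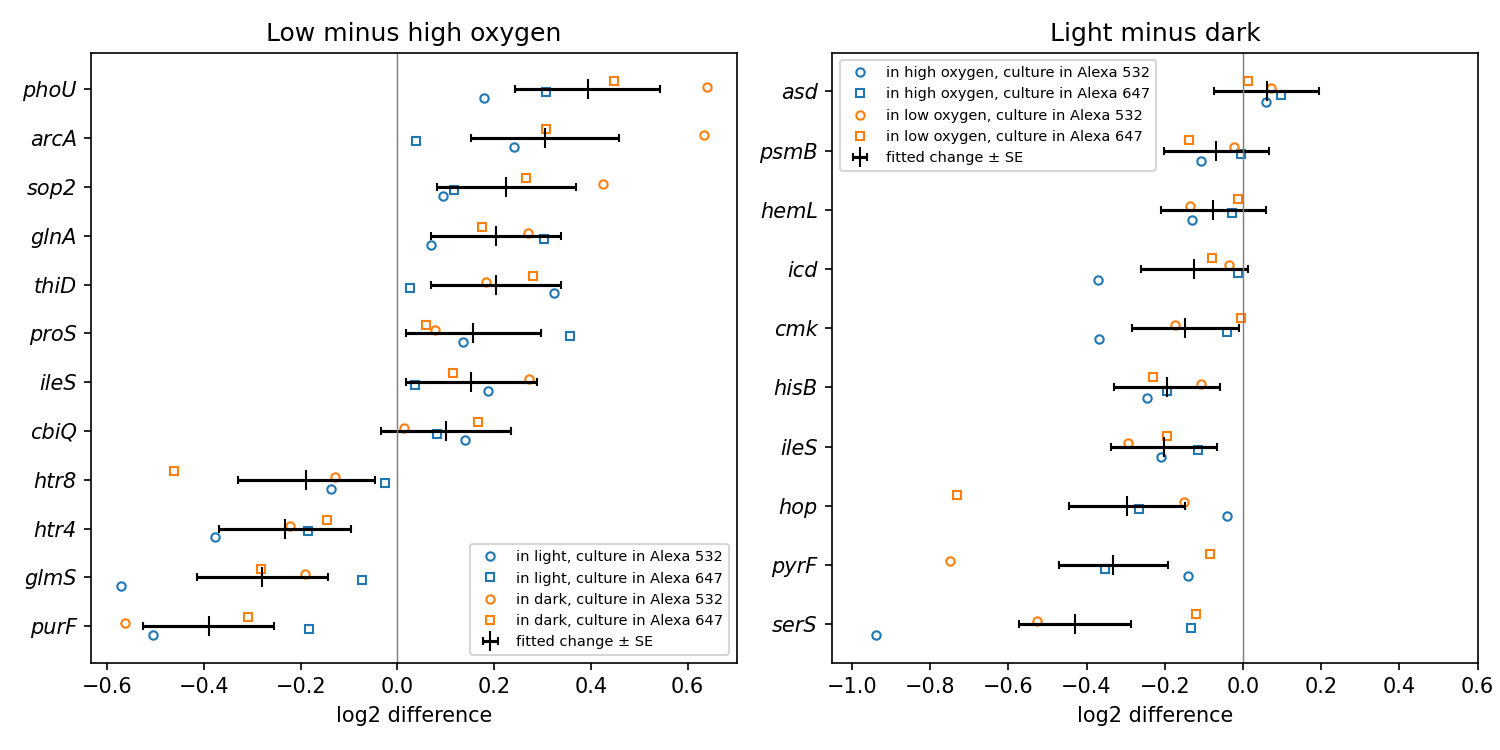
Log2 differences between low and high oxygen (left) and between light and dark (right). Genes are the named ones with usable signal and 1 sign in all 4 array differences. Open symbols are single array differences within a stratum of the other factor (colour) and a dye orientation (shape). Black bars are the fitted change ± SE. Fitted changes run from −0.39 for purF to 0.39 for phoU on the left and from −0.43 for serS to 0.06 for asd on the right.

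By group, the taxis transducers, membrane proteins that pass signals to the flagellar motor, had a median log2 change of −0.14 between low and high oxygen, with 5 of 7 members below 0. Their members htr18 (−0.34 ± 0.20), htr4, htr8 and htr7 (−0.14 ± 0.13) were lowest. Without single arrays htr18 ran from −0.53 to −0.15, htr8 from −0.26 to −0.11 and htr7 from −0.32 to 0.038. htr8 is known as an aerotaxis transducer. The list did not pass in camera (p = 0.0291, adjusted p = 0.116; p = 0.297 with an estimated correlation). Its median lay at percentile 0.39 of random lists, which passes at an adjusted p of 0.0312. The random lists draw single features, so that this leaves out the spread between cultures and any correlation between members. Only 1 member, htr6, was among the bright features, at 0.09 ± 0.14, so that the values below 0 came from dimmer members. With the dimmest 25% of features left out camera's adjusted p was 0.0239. Without high-oxygen light replicate 2 the median turned to 0.04, and in the authors' table it was −0.04.

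Over all 2688 features the median was 0.046 for oxygen, so that a count of members above 0 starts from a small shift of the whole array. Purine synthesis genes showed no common direction in the oxygen comparison, with 3 of 7 members above 0 and a median of −0.02 against a mean of 0.02 ± 0.27 (SD over genes). Beside purF, purL had 0.15 ± 0.13 and guaB −0.11 ± 0.16. In the tricarboxylic acid cycle, 4 of 6 genes were above 0 (median 0.03), including sucC at 0.10 ± 0.16, lpdA at 0.10 ± 0.14 and citZ at 0.05 ± 0.17, while mdh had −0.18 ± 0.17. Of the chaperone and proteasome list 5 of 6 were above 0 (median 0.06, and −0.048 with the culture in Alexa 647 alone, −0.024 on the low-gain scan and −0.0075 without background correction). In this list pan1 had 0.22 ± 0.17 (0.068 to 0.38 with 1 array left out), with dnaJ at 0.10 ± 0.15 and dnaK at −0.14 ± 0.16. This list holds panB, at 0.16 ± 0.15, which its symbol pattern took in although it belongs to pantothenate synthesis. camera's adjusted p was 0.836 for each of these 3 lists. Adjusted over the list alone, 0 members of any list passed for oxygen, as over all features.

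The remaining lists had fewer than 5 named members and were not tested as sets. In arginine fermentation arcA stood beside arcC (carbamate kinase) at 0.05 ± 0.17. In the respiratory chain sdhC had −0.12 ± 0.14 and nuoL 0.05 ± 0.15. Of the chemotaxis proteins cheY had −0.08 ± 0.13, cheA −0.03 ± 0.13, cheB −0.03 ± 0.13 and cheR 0.0028 ± 0.15. Pyrimidine genes lay between −0.0068 and 0.21, with pyrB at 0.21 ± 0.17, carB at 0.06 ± 0.13 and pyrI at 0.05 ± 0.15. Of the cobalamin genes cobN had −0.14 ± 0.15, cbiT −0.09 ± 0.14 and cbiG −0.05 ± 0.14. The haem genes hemA and hemL had −0.11 ± 0.17 and −0.02 ± 0.13. The oxidative stress genes msrA and dpsA had 0.07 ± 0.16 and 0.03 ± 0.13. Among repair genes uvrB had −0.01 ± 0.13, and uvrA had 0.00057 ± 0.14. The ribosomal gene rpl12p had −0.11 ± 0.31, and in the light sensor and pump list sop1 had 0.15 ± 0.16 and hop −0.04 ± 0.15. The only member of the carotenoid and retinal list, a regulator of the bacteriorhodopsin gene, had no usable signal.

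The second comparison asks which genes differ between light and dark. Of the named genes with usable signal and 1 sign in all 4 array differences, serS had the lowest log2 change (light minus dark). This gene, for seryl-tRNA synthetase, stood at −0.43 ± 0.14 (SE, 1.35-fold). pyrF, with its dim signal, stood at −0.33 ± 0.14, and hop, for the light-driven chloride pump halorhodopsin, at −0.30 ± 0.15 (1.23-fold). ileS (isoleucyl-tRNA synthetase) and hisB (histidine synthesis) had −0.20 ± 0.14 and −0.19 ± 0.13. None of these passed the test with n = 4 cultures, and the adjusted p in limma was 0.721 or more. With the culture in Alexa 532 alone serS had −0.73, and in Alexa 647 alone −0.13. Without single arrays serS ran from −0.59 to −0.27 and hop from −0.44 to −0.16. The pyrF value turned above 0 under 5 alternatives, so that its direction was not settled.

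limma called 0 of 2688 features for light, 173 had an unadjusted p under 0.05 (134.4 by chance), and the lowest adjusted p was 0.721. The same sign in all 4 array differences was found for 373 features (13.9%, with 12.5% for independent signs). Of the 10 named genes with usable signal that had it, 9 were below 0 and 1 was above 0. These include cmk (cytidylate kinase) at −0.15 ± 0.14, icd (isocitrate dehydrogenase) at −0.12 ± 0.14, hemL at −0.08 ± 0.13, the proteasome gene psmB at −0.07 ± 0.13 and asd (aspartate semialdehyde dehydrogenase) at 0.06 ± 0.13. With 1 array left out cmk ran from −0.24 to −0.057, icd from −0.18 to −0.064, hemL from −0.14 to −0.017 and asd from −0.023 to 0.14. Alternatives turned asd to −0.053, hemL to 0.0046 and hisB to 0.060. Among unnamed features, those starting at spots 4163 and 521 had 0.75 ± 0.25 and 0.53 ± 0.24, and those at spots 2103 and 1841 had −0.68 ± 0.14 and −0.66 ± 0.13, with adjusted p-values of 0.721, 0.731, 0.721 and 0.721.

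No list passed in the light comparison, where the median of all features was −0.033. The taxis transducers had 6 of 7 members above 0 (median 0.05), with htr18 at 0.25 ± 0.20, htr8 at 0.15 ± 0.14 and htr2 at 0.06 ± 0.14, and htr7 at −0.29 ± 0.13. In the authors' table their median was −0.02. With 1 array left out htr18 ran from 0.064 to 0.44, htr8 from 0.073 to 0.22, htr2 from 0.0084 to 0.11 and htr7 from −0.47 to −0.11. The tricarboxylic acid cycle had 5 of 6 below 0 (median −0.04), with lpdA at −0.11 ± 0.14, sucC at −0.05 ± 0.16 and mdh at 0.16 ± 0.17 beside icd. Purine genes had 5 of 7 below 0 (median −0.07), with purF at −0.14 ± 0.14, purD at −0.12 ± 0.13 and purL at −0.07 ± 0.13. Of the chaperone and proteasome list 3 of 6 were below 0, with pan1 at −0.26 ± 0.17, panB at −0.15 ± 0.15 and dnaJ at 0.08 ± 0.15. camera's adjusted p was 0.984 for each of the 4 lists, and adjusted over the list alone 0 members passed.

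In the lists with fewer than 5 named members, all 4 chemotaxis genes were above 0 in light, with cheA at 0.14 ± 0.13, cheY at 0.12 ± 0.13, cheR at 0.04 ± 0.15 and cheB at 0.02 ± 0.13. Beside hop, sop1 had 0.01 ± 0.16. arcC and arcA had 0.14 ± 0.17 and 0.03 ± 0.15, and nuoL and sdhC had 0.08 ± 0.15 and 0.04 ± 0.14. The pyrimidine genes lay between −0.13 and −0.0017, with pyrB at −0.13 ± 0.17. hemA had 0.19 ± 0.17, cobN 0.10 ± 0.15, cbiG 0.07 ± 0.14 and cbiT −0.06 ± 0.14. The repair genes uvrB and uvrA had 0.07 ± 0.13 and −0.06 ± 0.14, the stress genes msrA and dpsA −0.0087 ± 0.16 and −0.0043 ± 0.13, and rpl12p had −0.10 ± 0.31.

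The third comparison asks whether the oxygen difference depends on light. The highest interaction values among named genes were those of rpmC and rpl12p. Both genes, for proteins of the large ribosomal subunit, had log2 differences between low and high oxygen above 0 in light, at 0.68 and 0.51. In dark the values were −0.99 and −0.74. Relative to the reference, rpl12p stood at −0.62 in high oxygen and light, 0.10 in high oxygen and dark, −0.11 in low oxygen and light and −0.63 in low oxygen and dark. infB, for a translation initiation factor, had 0.25 in light and −0.49 in dark, and thrS, for threonyl-tRNA synthetase, 0.34 and −0.32.

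The interaction values (oxygen difference in light minus that in dark) were 1.67 ± 0.50 for rpmC, 1.25 ± 0.04 for rpl12p, 0.74 ± 0.12 for infB, 0.67 ± 0.09 for gdhA1 (glutamate dehydrogenase) and 0.66 ± 0.03 for thrS. The errors are technical only, the difference between both dye orientations divided by 2. The lowest among named genes with usable signal and 1 sign in both orientations were htr18 at −0.67 ± 0.42 and hisG (histidine synthesis) at −0.61 ± 0.45. After them came arcC at −0.44 ± 0.27, msrA (methionine sulfoxide reductase) at −0.40 ± 0.22 and thiC (thiamine synthesis) at −0.40 ± 0.04. With 1 culture per combination no residual degree of freedom is left, and the interaction was not tested. Over all features 50.5% had 1 sign of the interaction in both orientations, close to the 50% of independent signs, and of the named genes with usable signal 57 (55.9%). With 1 array left out, htr18 ran from −1.05 to −0.29, hisG from −1.05 to −0.17, arcC from −0.61 to −0.27, msrA from −0.79 to −0.013, thiC from −0.54 to −0.25 and rpmC from 1.26 to 2.09.

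**Figure D3:**
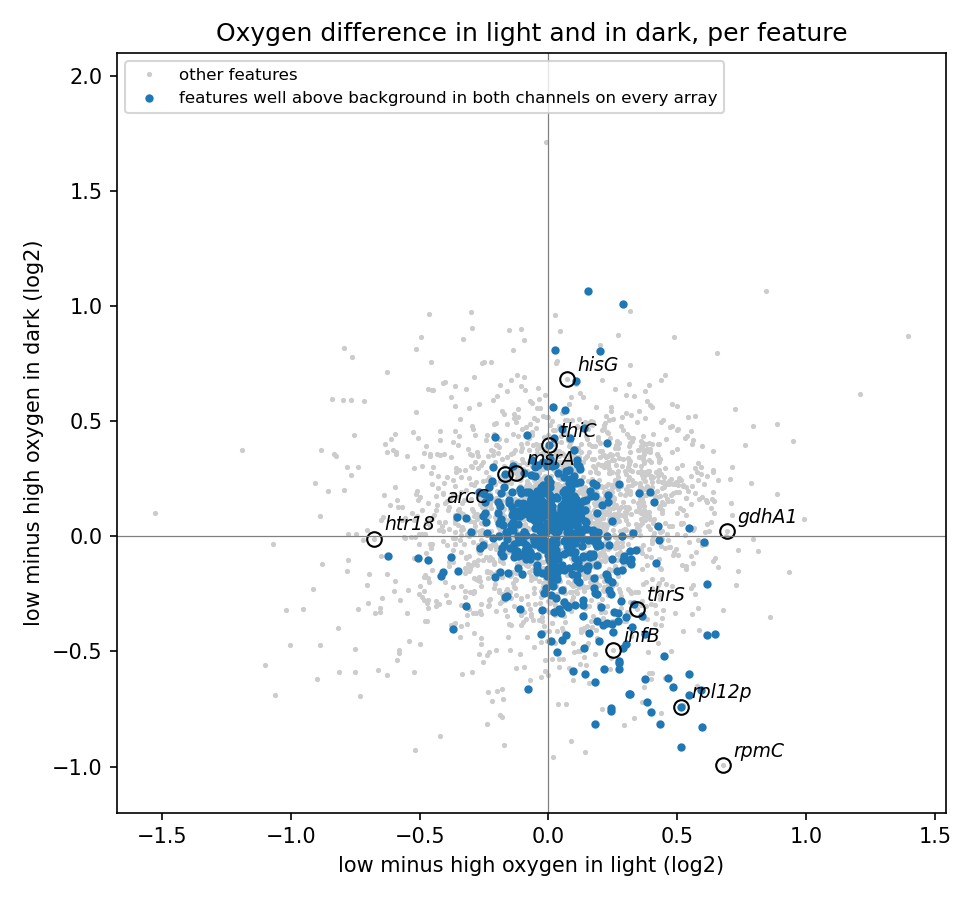
Difference between low and high oxygen (log2) in light (horizontal) and in dark (vertical) for each of the 2688 features; blue points are the 539 bright features, and circles mark the genes with the highest and lowest interaction values. rpl12p, a bright feature, and rpmC, which is not among them, lie at the lower right, and across the bright features the 2 differences had r = −0.345.

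Across all 2688 features the oxygen difference in light and that in dark correlated at r = 0.0352 (Spearman 0.0408), and the light difference in high oxygen and that in low oxygen at r = 0.0385 (Spearman 0.0510). Features are not independent replicates, and no p is given. Across the 539 bright features, rpl12p among them, the values were r = −0.345 (Spearman −0.259) and r = −0.507 (Spearman −0.380). In the same features the oxygen difference correlated between dye orientations at 0.303 in light and 0.621 in dark, and the interaction at 0.587. The Spearman values were lower, at 0.177, 0.483 and 0.404. Over all features the interaction correlated between orientations at 0.0347. With plain background subtraction the correlations over all features were −0.271 for oxygen and −0.323 for light. Within arrays of a single orientation, the oxygen differences in light and dark correlated at 0.118 (culture in Alexa 532) and −0.0715 (Alexa 647) over all features, and at −0.240 and −0.278 over the bright ones. Of the bright features, 119 moved in opposite directions in light and dark on all arrays (22.1%). Independent signs would give 12.5%, but both arrays of a culture hold the same RNA, so that spread between single cultures alone can raise this share. Like rpl12p, 85 of these were above 0 in light and below 0 in dark, and 34 had the reverse.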

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

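The tests of explanations in this part were chosen only after the results had been seen. The genes come from the rule for interaction values, and the differences between strata were not tested, since each combination is 1 culture.

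The oxygen difference went 1 way in light and the other way in dark on every array for rpmC (interaction 1.67), rpl12p (1.25), infB (0.74), thrS (0.66) and arcC (−0.44). The light difference did so between low and high oxygen for rpmC, rpl12p and infB, with the same 3 interaction values, and for msrA (−0.40). Of all features 13.5% did this for oxygen and 16.1% for light, and of the bright features 22.1% and 26.3%. Independent signs would give 12.5%, but both arrays of a culture hold the same RNA, so that spread between single cultures alone can raise these shares without any dependence on light or oxygen.

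The first pattern weighed is that oxygen differences in light and in dark do not follow each other. Over all 2688 features measurement noise alone may account for it, because the oxygen differences correlated between dye orientations at only 0.0417 in light and 0.0326 in dark. Within the 539 bright features noise alone is argued against, since the lower of these correlations was 0.303 (Spearman 0.177). Saturation of bright spots is argued against there as well, by the low-gain scan with 8 saturated spots left. It gave r = −0.311 between the differences in light and dark for the same features (bootstrap 95% interval over features from −0.403 to −0.216). Features share the same cultures and are not independent replicates, so that this interval may be too narrow. An oxygen response that depends on light stays open, since the interaction correlated at 0.587 (Spearman 0.404) between orientations in the bright features. Cultures that differed for any other reason, such as the moment of harvest, could give this too. With 1 culture per combination these cannot be told apart.

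The second pattern is that sop2 gave signal in all 4 cultures labelled as its deletion. With the culture in Alexa 647 a signal at the local background is argued against, since the lowest value was 2.52 times the background. With the culture in Alexa 532 the highest value was 1.44 times the background, but this cannot decide the question. In that dye htr2, not labelled as deleted, lay lower than sop2 on every array, at 0.967 to 1.33 times. sop1 and htr1, not labelled as deleted either, lay above sop2 on every array, at 1.21 to 1.49 and 1.21 to 1.52 times. The sop2 signal was there at percentiles 56.4 to 71.0 of the culture signals of all features. RNA from a gene still present in these cultures, RNA from a part outside the deletion and hybridisation of other RNA to the probe cannot be told apart by the log2 ratio of 0.10 ± 0.15 (SD, n = 4 cultures), since neither the probe position nor a culture of the parent strain was used here.

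The third pattern is that ratios of culture over reference opposed each other between dye orientations, with r from −0.492 to −0.438 for the arrays of a culture, while arrays of 1 orientation correlated at 0.693 to 0.888. In the bright features the opposition was weak, with r from −0.249 to 0.108 (median −0.108) between arrays of opposite orientation. Dye labels of one set of arrays being the wrong way round is argued against by the differences between cultures, which correlated between orientations at 0.448 ± 0.192 (mean ± SD of 4 differences, bright features). A bias of single probes for 1 dye and a difference between print or hybridisation runs cannot be told apart, since each orientation is 1 run of array numbers and either gives the r of 0.946 between the orientation differences of 2 pairs of cultures. No biological explanation was tested.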

How the results depend on the processing

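The alternatives of a low-gain scan, bright features alone, named features alone and the authors' empty spots left out were chosen after the data had been seen, and the cause of the differences below was not tested. The number of features called for oxygen, 0, was 1 in the authors' table (the unnamed feature at spot 4845, adjusted p = 0.0453) and 0 to 2 when single arrays were left out. The 2 features of spots 4845 and 4813 were called without low-oxygen light replicate 1. Light gave 0 calls in every alternative run. With the replicate block, where the number stands for the dye orientation, the 8 arrays gave 0 calls for oxygen and 0 for light, both with the culture as a random block (consensus correlation −0.262) and with arrays taken as independent. The number of lists shifted by oxygen, 0, was 1 with the dimmest 25% left out and 1 against random lists, the taxis transducers in both. The random lists leave out the spread between cultures. The lowest adjusted p of the alternatives lay between 0.0239 and 0.877. camera with an estimated correlation called 0 lists (adjusted p = 0.867), but on 1 residual degree of freedom it could hardly call any. Changes per feature correlated with the reported ones at 0.364 for oxygen and 0.465 for light without background correction, at 0.211 and 0.192 with plain subtraction, at 0.378 and 0.282 on the low-gain scan and at 0.396 and 0.540 in the authors' table.

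The correlation of the oxygen difference in light with that in dark (0.0352) was 0.101 without background correction, −0.271 with plain subtraction, −0.0161 with median centring, −0.0124 in the authors' table, 0.118 and −0.0715 with the culture in Alexa 532 or Alexa 647 alone, −0.137 on the low-gain scan, −0.345 for bright and −0.176 for named features, and −0.0668 to 0.101 with single arrays left out. That of the light differences (0.0385) was −0.0843, −0.323, 0.0872 with scaling between arrays, −0.0240 without the dimmest 25%, −0.185 in the authors' table, −0.167 in Alexa 647 alone, −0.236 on the low-gain scan, −0.507 for bright and −0.188 for named features, and −0.0988 to 0.134 with single arrays left out, the first pair being no correction and plain subtraction. The correlation of the interaction between orientations (0.0347) was 0.150 without correction, 0.127 with plain subtraction, −0.140 with median centring, 0.138 with scaling, 0.0744 without the dimmest 25%, 0.335 on the low-gain scan, 0.587 for bright and 0.261 for named features.

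The mean log2 ratio of sop2 was −0.071 on the low-gain scan, and 0.06 to 0.13 with single arrays left out. That of pyrF was 0.060 without correction, 0.20 with plain subtraction and 0.13 on the low-gain scan, and −0.45 to −0.11 with single arrays left out. Of 22 changes named for 1 sign in all array differences, 15 kept their sign throughout. This choice fixed their sign for a single dye orientation, so that those alternatives could not turn them. Changes of the variance prior, the threshold or the set of features, and arrays taken as observations, cannot move a log2 change. In the authors' table thiD had −0.043 for oxygen, and asd −0.053 and pyrF 0.036 for light. On the low-gain scan proS had −0.027 and ileS −0.20 for oxygen, and asd −0.0021, hisB 0.060 and pyrF 0.16 for light. For light pyrF had 0.18 without correction and 0.0095 with plain subtraction, hemL 0.0046 with plain subtraction and hisB 0.0056 with median centring. With single arrays left out asd ran from −0.023 to 0.14 and pyrF from −0.67 to 0.010. Of the other 91 changes of list members, 20 kept their sign in every alternative that measured them. Of the 10 interaction values, 9 did so, and hisG had 0.16 on the low-gain scan. They were chosen for 1 sign in both orientations, so that a single orientation could not turn them. The 91 changes were not chosen by sign, so that these counts cannot be compared. Where an array was left out, its culture was adjusted for the dye orientation by the other cultures.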

Other observations

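The values and tests in this part were chosen after the data had been seen. Of 12 genes of aminoacyl-tRNA synthetases, which load amino acids onto tRNA, 11 had a light minus dark value below 0, with a median log2 change of −0.10 and a mean of −0.14 ± 0.14 (SD over genes), and 0 passed in limma. Neither did the list. Beside serS (−0.43 ± 0.14, SE), thrS had −0.31 ± 0.20, lysS −0.26 ± 0.13 and pheS −0.21 ± 0.15. With 1 array left out, lysS ran from −0.47 to −0.054 and pheS from −0.37 to −0.056. camera gave p = 0.0682 (adjusted over both added lists 0.136), and p = 0.344 with an estimated correlation, and the median lay at percentile 14.2 of random lists. Of the 27 alternatives 19 moved the median, which ran from −0.19 to −0.0088, and camera's p ran from 0.00126 without background correction to 0.679 with 2 bright members alone. In the oxygen comparison 7 of the 12 were above 0 (median 0.01).

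All 6 histidine synthesis genes were above 0 for low minus high oxygen (median 0.08) and below 0 for light minus dark (median −0.09), and 0 passed. hisG had 0.38 ± 0.19 and hisF 0.23 ± 0.15 for oxygen, and hisB −0.19 ± 0.13 and hisG −0.13 ± 0.19 for light. With 1 array left out, hisG ran from 0.16 to 0.60 and hisF from −0.031 to 0.50 for oxygen, and hisB from −0.29 to −0.097 and hisG from −0.35 to 0.093 for light. camera did not call the list in either comparison. The medians lay at percentiles 69.7 and 38.6 of random lists, beside medians of all features of 0.046 and −0.033. The oxygen median turned to −0.054 with the culture in Alexa 647 alone, −0.022 with plain subtraction and −0.0038 without high-oxygen light replicate 1, and the light median to 0.018 on the low-gain scan. None of the 6 was among the bright features.

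Set against the common reference, which is NRC-1 grown to mid-log phase and no control culture, 666 of 2688 features passed in limma, 455 higher and 211 lower, 21 of them named. The same sign on all 8 arrays, which are 4 RNAs hybridised in both orientations against 1 reference, was found for 234 features, and 11 of these were named genes with usable signal. folP, of folate synthesis, had the highest mean log2 ratio, at 1.19 ± 0.22 (SD, n = 4 cultures; limma adjusted p = 0.00254), and the transducer gene htr6 had 0.27 ± 0.08 (adjusted p = 0.0497). Lower than the reference were purF at −0.43 ± 0.24 (adjusted p = 0.0149), phnE at −0.28 ± 0.17 (adjusted p = 0.0399) and glyA, for serine hydroxymethyltransferase, at −0.27 ± 0.08 (adjusted p = 0.0492). The others, which did not pass, were cheA at 0.12 ± 0.08, thiC at −0.29 ± 0.18, sucD at −0.23 ± 0.09, guaB at −0.21 ± 0.13, pheA at −0.14 ± 0.07 and psmB at −0.10 ± 0.04. Under 5 other settings of background, normalisation and scan, pheA and guaB turned sign once each and the other genes kept theirs. folP ran from 0.17 to 1.81, htr6 from 0.14 to 0.41, purF from −0.48 to −0.060, phnE from −0.19 to −0.052 and glyA from −0.28 to −0.077. These p-values leave out the spread of the reference itself. A bias of dye or run left after averaging the orientations is shared by all 4 cultures and does not enter them either. The 666 features are therefore not a count of transcripts that differ from the reference, and only 234 features had the same sign on all 8 arrays.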
